A study of Mus musculus with 17 samples.

How the data were processed

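Gene expression was measured by RNA sequencing in 17 libraries of sorted brain myeloid cells from C57BL/6J mice, in 4 groups: transplanted µ (3), transplanted TAµ (3), adult control µ (3) and P10 TAµ (8). The design text of the series speaks of triplicates, whereas the labels list 8 P10 libraries. The labels do not spell out µ, TAµ or BU, and do not say whether the sorted cells of transplanted mice carried GFP. Per the labels' protocols, 100 ng of RNA extracted with the RNeasy Plus Micro kit was amplified with the Ovation RNA-Seq System V2, made into Ovation Ultralow libraries and sequenced on an Illumina HiSeq instrument as single-end reads of 50 cycles, at an average of 30 M clusters. Per the submitters' processing notes, reads were aligned to mm10 with STAR 2.3.0, assigned to genes with HTSeq 0.5.3 and compared with limma. The normalization, the filter on genes, the annotation and the settings of limma are not given in the sources used here.

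A single table of 13769 genes was used, which holds the authors' comparisons and no values per library. Its log2 average expression and log2 fold changes between groups were made by the authors with limma, per the file headers. Its p-values and Benjamini-Hochberg adjusted p-values come from the authors' limma fit, per the file headers, and 259 genes have a p listed as 0 in at least 1 comparison. Its score columns, a moderated F over the 4 groups and a call of 1, 0 or -1, were deposited by the authors, per the file headers. F passed an adjusted p of 0.05 for 7194 genes in the authors' deposited table. The headers do not give the sign of the fold changes. It was settled from the proliferation genes, which stand higher in P10 cells when the first-named group is read as the one the coefficient is positive for.

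The counts of genes past an adjusted p of 0.05 describe the authors' deposited table, as planned for a file of comparisons alone. Standard errors were recovered from each fold change and its p, with 18 degrees of freedom solved from F and its p in 2343 genes. For the smallest p-values the adjusted p and its rank were used. Recovered group variances added across pairs of comparisons to a ratio between 0.9997 and 1.0003 at the 1st and 99th percentiles. The difference of the transplant effects was planned as described and not tested where only comparisons were deposited, and its test, on 13720 genes, was added after the table was seen. In this test 49 genes without a recovered standard error were left out. The method was tested on simulated data of 13769 genes fitted with limma. It returned 99.99% of the interaction standard errors within 1% and the same call as limma for 100.0% of genes. Of 100 genes simulated with a 2-fold change 8.0% were called, and of 100 with a 4-fold change 62.0%, with 9 unchanged genes called and 0 calls of the wrong sign. Only these genes were changed, in transplanted µ alone, whereas 13.3% of the genes tested were called in the data. The adjusted p depends on how many genes change, so these rates are not the sensitivity of the test in the data. The median interaction standard error of genes above the median expression was 0.41 in that simulation and 0.51 in the data. Of 200 random lists tested with cameraPR, 3 were called at 0.05. The simulated genes were drawn independently of each other, so this count does not cover lists of correlated genes. A planted list had a cameraPR p of 1.9e-07. The recovered standard errors had a median of 0.62 for transplanted µ against adult control µ, 0.57 for transplanted TAµ against P10 TAµ, 0.68 for TAµ against µ, 0.49 for P10 TAµ against adult control µ and 0.87 for the interaction, which is the precision that these libraries gave. Totals per library were not analysed here.

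26 lists of genes, 478 genes in all with 402 measured, were fixed before the data were seen, as were the rules for naming genes. Lists with at least 3 measured members were tested with cameraPR of limma 3.58.1 on the moderated statistics, with a correlation of 0.01 between genes and Benjamini-Hochberg adjustment over 125 tests. An estimated correlation is not possible without values per library, so presets of 0 and 0.05 and the rank-based form were run beside it. Named genes are the 15 fixed markers, the 5 largest rises and 5 largest falls past adjusted p 0.05 among genes of at least median average expression, without predicted genes and clone names, and up to 2 members of each list in each direction with the smallest adjusted p. Some genes that this rule names are not reported here. Malat1, mt-Co1, Xist and the Y-linked genes were chosen after their values were seen. Lists adjusted over the list alone used Benjamini-Hochberg over the members of that list. Alternatives were an expression filter at the first quartile, a threshold of 0.01, a minimum absolute log2 fold change of 1, Bonferroni adjustment and 1 entry per symbol, and after the data were seen centring on the median fold change and a filter at the median expression. The first form of the test for a common share of TAµ-like cells used only genes 16-fold or more above the control, and it is given beside the full form. Gene lengths and positions come from GENCODE M21 on mm10. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.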

Results

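RNA sequencing was carried out on sorted myeloid cells of the C57BL/6J mouse brain, from populations that the labels name µ and TAµ without spelling the names out. The 17 libraries fell into 4 groups. Transplanted µ (3 libraries) and transplanted TAµ (3 libraries) came from BU-treated mice 3 months after transplantation of GFP Lin- cells. Adult control µ (3 libraries) came from mice 5 months old and P10 TAµ (8 libraries) from mice at postnatal day 10. The title of the series asks how far brain myeloid cells that arise from transplanted stem and progenitor cells resemble microglia, the resident macrophages of the brain. Values are log2 fold changes of the authors' deposited table, which lists 13769 genes, each given as the first-named group minus the second. The number after ± is a standard error recovered from the fold change and p of that table. "Higher" and "lower" are used of genes past the table's limma adjusted p of 0.05. The transplanted fractions carry matching sample letters, whereas they and each control came from mice that differ in age or treatment, so between these a batch or day of preparation cannot be told apart from the group.

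**Figure D1:**
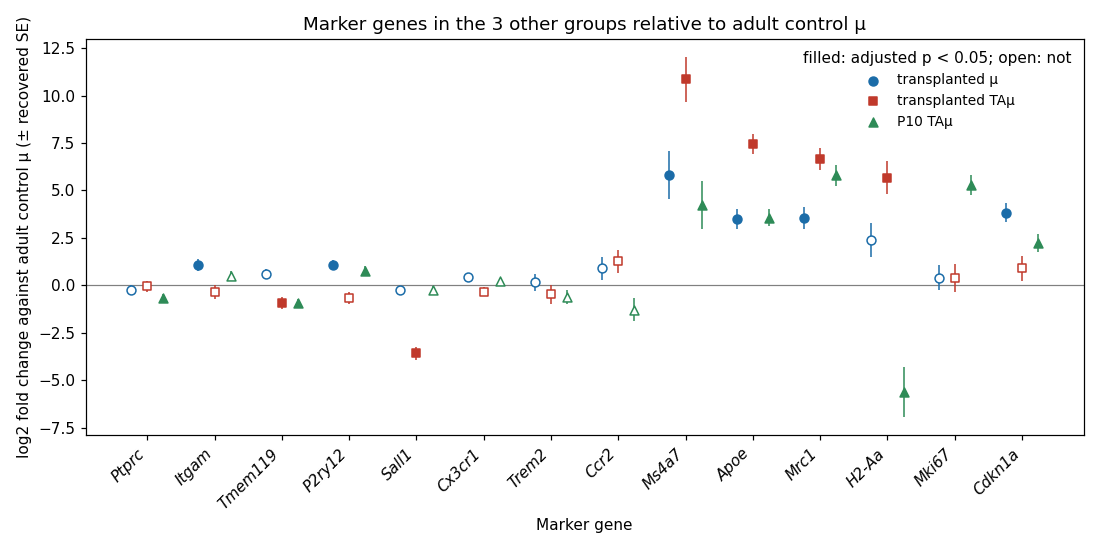
Log2 fold change of 14 marker genes against adult control µ in the authors' deposited table, for transplanted µ (circles), transplanted TAµ (squares) and P10 TAµ (triangles), with bars of ± 1 recovered standard error and filled symbols for an adjusted p under 0.05. Ms4a7, Apoe and Mrc1 lie above 0 in all 3 groups, Sall1 lies at -3.57 in transplanted TAµ, and H2-Aa lies at -5.64 in P10 TAµ.

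Transplanted µ was first compared with adult control µ. Macrophage genes were higher in transplanted µ in the authors' deposited table: Ms4a7, typical of macrophages derived from blood, by 5.82 ± 1.25 (adjusted p = 0.00406), and the apolipoprotein gene Apoe by 3.49 ± 0.51 (adjusted p = 0.000332). The mannose receptor gene Mrc1 was higher by 3.55 ± 0.59 (adjusted p = 0.000784) in the authors' deposited table. Among microglia genes, the purinergic receptor gene P2ry12 was higher by 1.06 ± 0.27 in the authors' deposited table. Sall1, a transcription factor of microglia, differed by -0.26 ± 0.23 (adjusted p = 0.441) and Tmem119 by 0.58 ± 0.26 (adjusted p = 0.120) in the authors' deposited table. Of the p53 response, Phlda3 was higher by 7.63 ± 0.78 (adjusted p = 1.9e-05) and the cell cycle inhibitor gene Cdkn1a by 3.84 ± 0.52 (adjusted p = 0.000175) in the authors' deposited table. Phlda3 has an average log2 expression of 0.11, under the first quartile of 0.88, so the size of its changes is uncertain, here and below. Immediate early genes, which cells switch on within minutes of a stimulus, were lower, with Egr1 at -4.60 ± 0.33 (adjusted p = 4.6e-07), Fosb at -5.28 ± 0.59 and Jun at -3.81 ± 0.38 in the authors' deposited table. Beside them, the nuclear RNA Malat1 was lower at -3.77 and the mitochondrial gene mt-Co1 higher by 1.74 in the authors' deposited table, both chosen after their values were seen.

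Of the 18 measured genes of the marrow-derived brain macrophage list, 10 were higher and 0 lower in the authors' deposited table, 14 and 0 adjusted over the list alone. The list had a cameraPR adjusted p of 1.81e-05. Of the 28 homeostatic microglia genes, 12 were higher, among them Pros1 at 1.52 ± 0.25 and Sparc at 1.52 ± 0.31, and 1 was lower, Sall3 at -0.73 ± 0.26, in the authors' deposited table. The counts were 12 and 1 adjusted over the list alone, with a cameraPR adjusted p of 0.00125. Of 19 border-associated macrophage genes 6 were higher and 0 lower in the authors' deposited table, 7 and 0 adjusted over the list alone. Here cameraPR gave an adjusted p of 0.0151, and an adjusted p of 0.0717 with the correlation preset at 0.05. Of 12 MHC class II genes 5 were higher and 0 lower, with H2-DMa at 1.27 ± 0.29 and Ctss at 1.20 ± 0.28, in the authors' deposited table. The counts were 6 and 0 adjusted over the list alone, with a cameraPR adjusted p of 0.0226 and an adjusted p of 0.0686 at the preset of 0.05. H2-Aa, a chain of the class II molecule that presents antigen to T cells, differed by 2.40 ± 0.90 (adjusted p = 0.0628) in the authors' deposited table.

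Of 17 p53 response genes, 7 were higher and 0 lower in the authors' deposited table, Ccng1 at 2.86 ± 0.32 among them. The counts were 8 and 2 adjusted over the list alone, with a cameraPR adjusted p of 0.000852 and an adjusted p of 0.0940 in the rank-based form. Of 30 lysosome genes, 19 were higher, such as Ids at 1.36 ± 0.24 and Ctsa at 0.80 ± 0.17, and 1 lower, Gla at -3.76 ± 1.15, in the authors' deposited table. Adjusted over the list alone they numbered 20 and 2, with a cameraPR adjusted p of 1.01e-05. Of 20 immediate early and dissociation stress genes, 17 were lower and 0 higher in the authors' deposited table, 18 and 0 adjusted over the list alone. This list had a cameraPR adjusted p of 1.2e-24. Beside them, 5 of 18 inflammatory cytokine genes were lower and 1 higher, with Nfkbiz at -4.36 ± 0.77 and Cxcl16 at 1.02 ± 0.27, in the authors' deposited table. Adjusted over the list alone these were 7 and 1, with a cameraPR adjusted p of 0.00475.

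Astrocyte, neuron and oligodendrocyte markers moved with these groups. Of 13 astrocyte genes 8 were higher, with the glutamate transporter gene Slc1a2 at 2.45 ± 0.52, and 0 lower in the authors' deposited table, 9 and 0 adjusted over the list alone (cameraPR adjusted p = 0.00121). Of 13 neuron genes 6 were higher, with the synaptic gene Snap25 at 3.17 ± 0.58, and 0 lower in the authors' deposited table, 9 and 0 adjusted over the list alone (cameraPR adjusted p = 0.00121). Of 12 oligodendrocyte genes 4 were higher, with the myelin gene Mbp at 2.54 ± 0.62, and 0 lower in the authors' deposited table, 6 and 0 adjusted over the list alone. Their cameraPR adjusted p was 0.0219, and the adjusted p was 0.0672 with the correlation preset at 0.05. Of 7 endothelial genes 0 were called in the authors' deposited table, and 0 adjusted over the list alone (cameraPR adjusted p = 0.819). Of 6 pericyte and smooth muscle genes 1 was higher and 1 lower in the authors' deposited table, 1 and 1 adjusted over the list alone (cameraPR adjusted p = 0.642). Of 7 erythroid genes 3 were higher and 0 lower in the authors' deposited table, 3 and 0 adjusted over the list alone (cameraPR adjusted p = 0.13). Of 7 stem and progenitor cell genes 2 were higher and 0 lower in the authors' deposited table, 2 and 1 adjusted over the list alone (cameraPR adjusted p = 0.555). Of 4 B cell genes 0 were called in the authors' deposited table, and 0 adjusted over the list alone (cameraPR adjusted p = 0.785).

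Among genes of at least median expression, the largest rises were Ccnd2 at 8.08 ± 1.48, Csrp1 at 5.81 ± 1.42, Fads2 at 5.72 ± 1.35, Vcam1 at 5.54 ± 1.33 and Nfib at 5.30 ± 1.16 in the authors' deposited table. Ccnd2 was also higher in P10 TAµ than in adult control µ, by 6.74 ± 1.46, so its rise is not particular to transplanted µ. With an average log2 expression of 3.51 its level in that control was low, and the size of these rises is uncertain. The largest falls besides Fosb were Klf2 at -5.43 ± 1.70, Neat1 at -5.20 ± 0.67, Rbm4b at -5.01 ± 1.19 and Adamts1 at -4.81 ± 0.79 in the authors' deposited table. Over all genes, 1557 were higher and 1440 lower in the authors' deposited table, 52.0% of the calls being higher. The median over all genes was 0.19, and with fold changes centred on it 1072 were higher and 1773 lower, 37.7% being higher. Centring turned the median of the interferon response list from 0.16 to -0.03 and that of the proliferation list from 0.18 to -0.01. It left 6 homeostatic microglia genes higher and 1 lower, and 11 lysosome genes higher and 2 lower. Median, mean and test differed in sign for the proliferation and dendritic cell lists, both without a cameraPR call.

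Transplanted TAµ was then compared with P10 TAµ, the TAµ cells of the developing brain. Antigen presentation genes were higher in the authors' deposited table: H2-Aa by 11.31 ± 1.10 (adjusted p = 1.62e-06) and the invariant chain gene Cd74 by 5.32 ± 0.34 (adjusted p = 1e-08). H2-Aa has an average log2 expression of 1.77, where the lowest of any gene is -3.77, so its level in P10 TAµ was near the floor. The size of its differences that involve P10 TAµ is therefore uncertain, here and below. Cybb, a subunit of the phagocyte NADPH oxidase, was higher by 6.67 ± 0.42 (adjusted p = 1e-08), Ms4a7 by 6.63 ± 0.51 and Apoe by 3.89 ± 0.38 in the authors' deposited table. Cell division genes were lower, with Mki67 at -4.87 ± 0.55 (adjusted p = 9.1e-06), Top2a at -3.87 ± 0.34 and Hmmr at -9.69 ± 1.08 in the authors' deposited table. Sall1 was lower at -3.34 ± 0.32 (adjusted p = 1.46e-06), beside the hexose transporter gene Slc2a5 at -2.74 ± 0.41 and P2ry12 at -1.44 ± 0.27, in the authors' deposited table. Tmem119 differed by -0.02 ± 0.27 (adjusted p = 0.959) in the authors' deposited table. The integrin gene Itga4, by 5.00 ± 0.47, and the chemokine receptor gene Ccr2, by 2.53 ± 0.53 (adjusted p = 0.00225), both typical of monocytes, were higher in the authors' deposited table.

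Of 18 marrow-derived macrophage genes 13 were higher and 0 lower in the authors' deposited table, 14 and 1 adjusted over the list alone (cameraPR adjusted p = 1.44e-28). Of 12 MHC class II genes 7 were higher and 0 lower in the authors' deposited table, 7 and 0 adjusted over the list alone (cameraPR adjusted p = 2.73e-16). Of 16 MHC class I genes 8 were higher, H2-K1 at 1.39 ± 0.31 among them, and 0 lower in the authors' deposited table, 8 and 0 adjusted over the list alone (cameraPR adjusted p = 0.00168). Of 25 interferon response genes 7 were higher, Bst2 at 2.46 ± 0.31 among them, and 0 lower in the authors' deposited table, 7 and 0 adjusted over the list alone (cameraPR adjusted p = 0.000481). Of 19 border-associated macrophage genes 8 were higher, with Stab1 at 2.11 ± 0.19, and 0 lower in the authors' deposited table, 9 and 0 adjusted over the list alone (cameraPR adjusted p = 1.06e-05). Of 16 monocyte genes 6 were higher and 1 lower in the authors' deposited table, 7 and 1 adjusted over the list alone (cameraPR adjusted p = 0.000553).

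Homeostatic microglia genes were lower in 16 of 28 cases and higher in 3, C1qa at 1.36 ± 0.31 among the latter, in the authors' deposited table. The counts were 17 and 3 adjusted over the list alone, with a cameraPR adjusted p of 0.00063. The sign of all fold changes was set so that proliferation genes are higher in P10 TAµ, so their direction against P10 TAµ is no finding. Proliferation genes were lower in 32 of 35 cases and higher in 0 in the authors' deposited table, 34 and 0 adjusted over the list alone (cameraPR adjusted p = 4.78e-17). Immediate early genes were lower in 12 of 20 cases, with Egr1 at -4.64 ± 0.39, and higher in 0 in the authors' deposited table, 12 and 0 adjusted over the list alone (cameraPR adjusted p = 1.63e-06). Amoeboid and disease-associated microglia genes went both ways, 3 higher and 8 lower of 21, with Anxa5 at 1.65 ± 0.25, Ctsl at -2.76 ± 0.24 and Lpl at -4.13 ± 0.60, in the authors' deposited table. Adjusted over the list alone they were 3 and 9, with a cameraPR adjusted p of 0.316. Dendritic cell genes were lower in 3 of 7 cases and higher in 0 in the authors' deposited table, 3 and 0 adjusted over the list alone. Their cameraPR adjusted p was 0.0335, the adjusted p was 0.0672 with the correlation preset at 0.05, and it was 0.0575 in the rank-based form.

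Astrocyte and neuron markers moved with the macrophage genes here too. Astrocyte genes were higher in 11 of 13 cases, with Slc1a2 at 3.93 ± 0.46, and lower in 0 in the authors' deposited table, 13 and 0 adjusted over the list alone (cameraPR adjusted p = 6.97e-13). Neuron genes were higher in 5 of 13 cases, with Snap25 at 3.90 ± 0.41, and lower in 0 in the authors' deposited table, 6 and 0 adjusted over the list alone (cameraPR adjusted p = 0.00475). Oligodendrocyte genes, with a median of -0.13, were higher in 3 of 12 cases and lower in 0 in the authors' deposited table, 3 and 0 adjusted over the list alone (cameraPR adjusted p = 0.0732). Erythroid genes were higher in 4 of 7 cases and lower in 1 in the authors' deposited table, 4 and 1 adjusted over the list alone (cameraPR adjusted p = 0.0654). Endothelial genes were lower in 3 of 7 cases and higher in 0 in the authors' deposited table, 4 and 0 adjusted over the list alone (cameraPR adjusted p = 0.136). Pericyte and smooth muscle genes were lower in 3 of 6 cases and higher in 1 in the authors' deposited table, 3 and 1 adjusted over the list alone (cameraPR adjusted p = 0.5).

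Between transplanted TAµ and P10 TAµ the largest falls among genes of at least median expression were Adamts1 at -8.50 ± 2.19, Nid2 at -8.18 ± 1.84, Myo18b at -7.18 ± 1.55, Tmem44 at -6.74 ± 1.39 and Layn at -6.73 ± 1.04 in the authors' deposited table. The largest rises among these genes besides Cybb were Fam107a at 6.45 ± 1.16, Vcam1 at 6.13 ± 0.54, Cp at 6.03 ± 0.55 and H2-Ab1 at 5.68 ± 0.56 in the authors' deposited table. In all, 1441 genes were higher and 2100 lower in the authors' deposited table, 40.7% of the calls being higher. The median over all genes was -0.33, and with fold changes centred on it 2183 were higher and 1435 lower, 60.3% being higher. Centring turned the median of the lysosome list from -0.12 to 0.21, that of the oligodendrocyte list from -0.13 to 0.19, and the p53 counts from 1 higher and 3 lower to 2 and 1. It left 10 homeostatic microglia genes lower and 3 higher, and 7 amoeboid genes lower and 5 higher. Median, mean and test differed in sign for the amoeboid, inflammatory cytokine, lysosome, transcription factor, stem cell and oligodendrocyte lists, all without a cameraPR call.

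**Figure D2:**
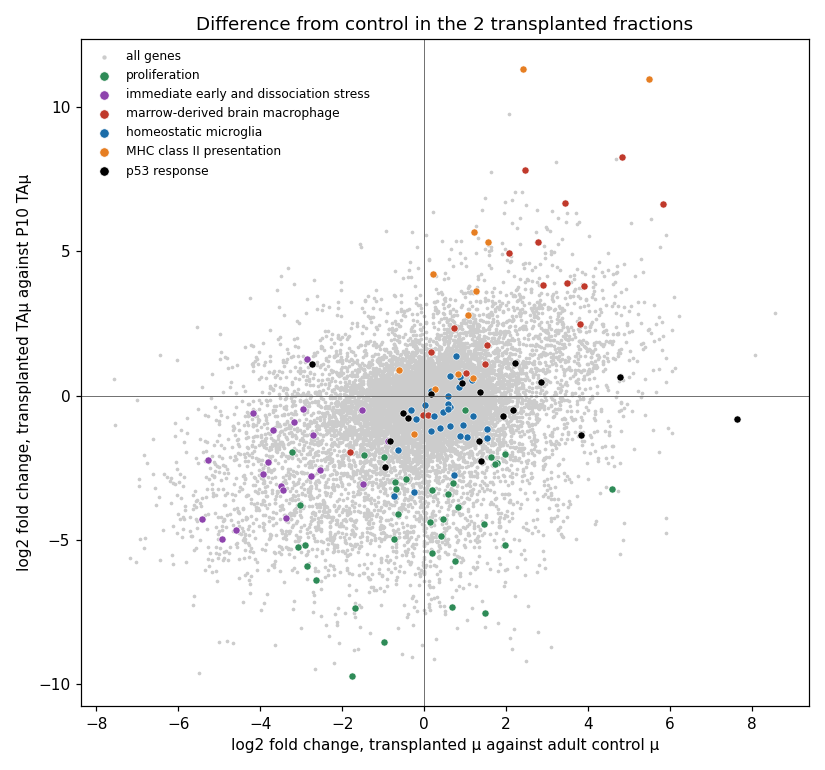
Log2 fold change of each of the 13769 genes between transplanted µ and adult control µ (horizontal axis) and between transplanted TAµ and P10 TAµ (vertical axis) in the authors' deposited table, with the members of 6 fixed gene lists in colour. Marrow-derived macrophage genes (red) have a median of 2.26 on the horizontal and 3.15 on the vertical axis, immediate early genes (purple) of -3.41 and -2.43, and proliferation genes (green) of 0.18 and -4.11.

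The comparisons of each transplanted fraction with its control share no group, and their calls overlapped. The transplanted fractions carry matching sample letters and can share mice, which neither the counts for independent lists nor the standard errors of the difference allow for. In both, 455 genes were higher in the authors' deposited table, where independent lists would share 162.9, and 439 were lower, where independent lists would share 219.6. Opposite calls numbered 133 and 53 in the authors' deposited table, against 237.5 and 150.7 for independent lists. Across genes, which are not independent replicates, the fold changes in the authors' deposited table had a Pearson r of 0.39 and a Spearman rho of 0.34. The difference between these effects, TAµ minus µ, was tested with the recovered standard errors. The controls differ in age, so this contrast carries their age difference as well as the transplantation. Of 13720 genes 1818 passed a limma-type adjusted p of 0.05, 515 with a more positive and 1303 with a more negative difference, 28.3% being more positive. The median difference was -0.50, and centred on it 1000 genes were more positive and 609 more negative, 62.2% being more positive. Derived from the authors' deposited table, Sall1 differed by -3.08 ± 0.40 (adjusted p = 0.000218) and Cdkn1a by -5.19 ± 0.71 (adjusted p = 0.000276). H2-Aa differed by 8.91 ± 1.42, again derived from the authors' deposited table.

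By list, the difference was more negative in TAµ for 15 of 28 homeostatic microglia genes and more positive for 0, 15 and 0 adjusted over the list alone (cameraPR adjusted p = 1.21e-09). For proliferation genes it was more negative in 18 of 35 and more positive in 0, 22 and 0 adjusted over the list alone (cameraPR adjusted p = 1.48e-09). Their medians were -4.11 in TAµ against P10 TAµ and 0.18 in µ against control, so this direction follows the choice of sign and is no finding. For p53 response genes the difference was more negative in 5 of 17 and more positive in 0, 7 and 1 adjusted over the list alone (cameraPR adjusted p = 0.00154). It was more positive for 7 of 12 MHC class II genes and more negative for 0, 8 and 0 adjusted over the list alone (cameraPR adjusted p = 3.07e-07). Marrow-derived macrophage genes had 6 of 18 more positive and 0 more negative, 6 and 0 adjusted over the list alone (cameraPR adjusted p = 0.000645). Centring left 9 homeostatic microglia genes more negative and 0 more positive. It turned the median of the border-associated macrophage list from -0.47 to 0.04, and for this list and the stem cell list, both without a call, median, mean and test differed in sign.

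Within the transplanted mice, TAµ was compared with µ. TAµ cells had more mRNA of macrophage genes in the authors' deposited table, with Ms4a7 higher by 5.03 ± 0.49 (adjusted p = 5.7e-05), Apoe by 3.97 ± 0.45 (adjusted p = 7.3e-05), Mrc1 by 3.12 ± 0.37 and the receptor tyrosine kinase gene Axl by 3.26 ± 0.35. Microglia genes were lower, Sall1 at -3.31 ± 0.35 (adjusted p = 6e-05), Slc2a5 at -3.69 ± 0.43, P2ry12 at -1.72 ± 0.31 and Tmem119 at -1.52 ± 0.31 in the authors' deposited table. Cx3cr1 was lower as well, at -0.79 ± 0.23 (adjusted p = 0.0492), in the authors' deposited table. The monocyte genes Itga4, by 4.93 ± 0.61, and F13a1, by 5.77 ± 1.02, were higher in the authors' deposited table, as were the platelet factor gene Pf4, by 4.74 ± 0.72, and the growth factor gene Igf1, by 4.61 ± 0.52. The p53 targets Cdkn1a, at -2.94 ± 0.52 (adjusted p = 0.0026), and Phlda3, at -3.43 ± 0.80 (adjusted p = 0.0162), were lower in TAµ than in µ in the authors' deposited table. Ptprc and Trem2 differed by 0.19 ± 0.30 (adjusted p = 0.758) and -0.62 ± 0.49 (adjusted p = 0.485) in the authors' deposited table, and Ccr2 by 0.37 ± 0.53 (adjusted p = 0.729).

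Homeostatic microglia genes were lower in 19 of 28 cases and higher in 0 in the authors' deposited table, 20 and 0 adjusted over the list alone (cameraPR adjusted p = 4.24e-24). Marrow-derived macrophage genes were higher in 11 of 18 cases and lower in 0 in the authors' deposited table, 14 and 1 adjusted over the list alone (cameraPR adjusted p = 5.54e-20). Border-associated macrophage genes were higher in 11 of 19 cases and lower in 0 in the authors' deposited table, 13 and 0 adjusted over the list alone (cameraPR adjusted p = 2.21e-16). Monocyte genes were higher in 5 of 16 cases and lower in 0 in the authors' deposited table, 5 and 0 adjusted over the list alone (cameraPR adjusted p = 0.000309). MHC class II genes were higher in 4 of 12 cases, with Cd74 at 3.15 ± 0.36 and H2-Aa at 3.27 ± 0.51, and lower in 0 in the authors' deposited table. Adjusted over the list alone they were 4 and 0, with a cameraPR adjusted p of 0.00289 and an adjusted p of 0.353 in the rank-based form. Interferon response genes were higher in 4 of 25 cases and lower in 0 in the authors' deposited table, 5 and 0 adjusted over the list alone. Their cameraPR adjusted p was 0.00538, and the adjusted p was 0.0524 with the correlation preset at 0.05.

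Amoeboid microglia genes were higher in 6 of 21 cases, with Gpnmb at 5.76 (adjusted p = 0.00234), and lower in 1, Cd9 at -1.95 ± 0.47, in the authors' deposited table. Their counts adjusted over the list alone were 9 and 1, with a cameraPR adjusted p of 0.0018 and an adjusted p of 0.0591 in the rank-based form. The p53 list had 4 of 17 genes lower and 1 higher, Plk2 at 3.61 ± 1.05, in the authors' deposited table, 5 and 1 adjusted over the list alone (cameraPR adjusted p = 0.00538). Erythroid and astrocyte transcripts moved with the macrophage genes. Of 7 erythroid genes 3 were higher, with Hba-a1 at 4.29 ± 0.88, and 0 lower in the authors' deposited table, 4 and 0 adjusted over the list alone (cameraPR adjusted p = 0.00433). Hba-a1 has an average log2 expression of -1.31, under the first quartile of 0.88, so the size of its change is uncertain. Of 13 astrocyte genes 2 were higher, S100b at 1.84 ± 0.51 and Gfap at 1.66 ± 0.48, and 0 lower in the authors' deposited table, 8 and 0 adjusted over the list alone (cameraPR adjusted p = 0.000101). The cameraPR adjusted p was 0.0659 for neuron, 0.577 for oligodendrocyte, 0.946 for endothelial and 0.944 for pericyte and smooth muscle genes, of which 1, an oligodendrocyte gene, was higher and 0 lower in the authors' deposited table. Of 20 immediate early genes 1 was lower, Rhob at -1.99 ± 0.41, and 0 higher in the authors' deposited table, 1 and 0 adjusted over the list alone (cameraPR adjusted p = 0.396).

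Over all genes 490 were higher and 404 lower in the authors' deposited table. Among genes of at least median expression, the largest falls were Zfp697 at -6.73, Layn at -6.36 ± 1.07, Sgce at -5.98 ± 1.13, Myo18b at -5.91 ± 1.63 and Arvcf at -5.83 ± 0.83 in the authors' deposited table. Among the same genes Nnat was higher by 5.69 ± 1.36 in the authors' deposited table. Median, mean and test differed in sign for the inflammatory cytokine, lysosome and endothelial lists, all without a cameraPR call. Both fractions carry matching sample letters, but a fit with the letter as a block was not possible from a table of comparisons.

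**Figure D3:**
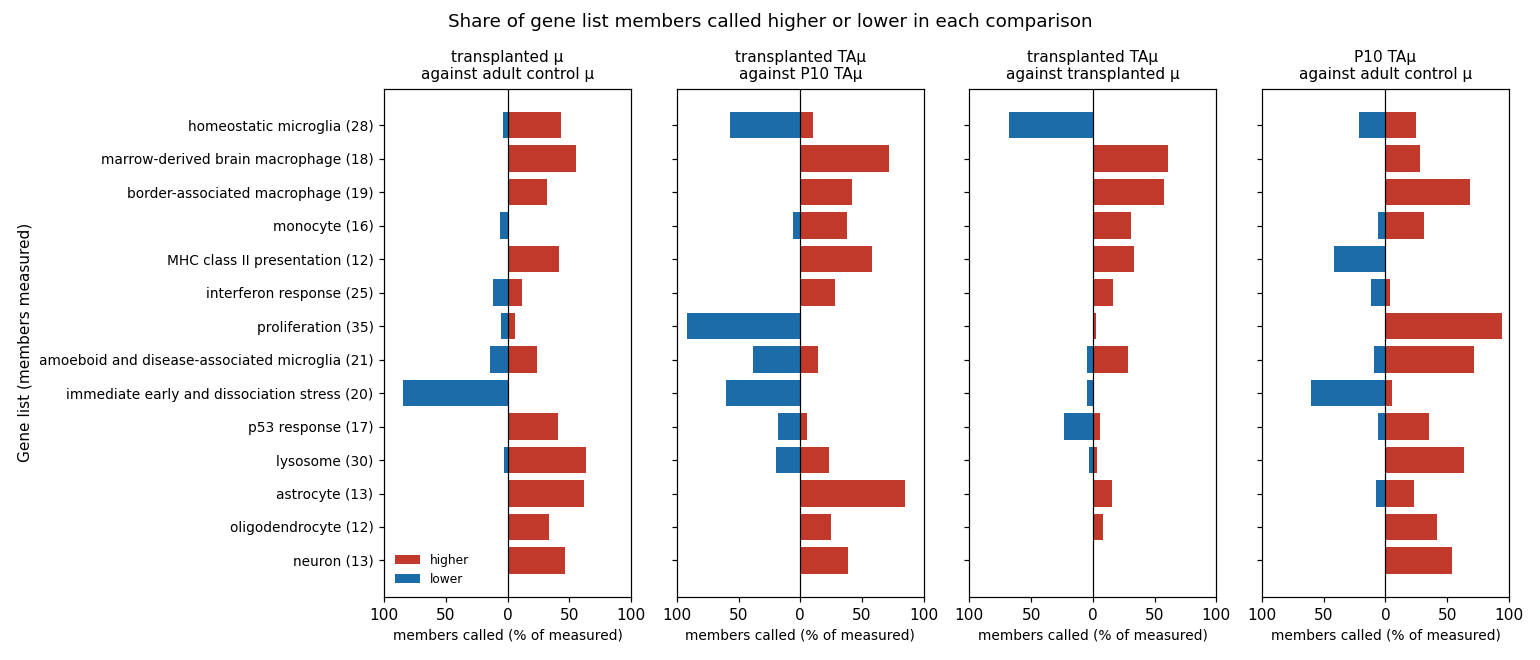
Percent of the measured members of 14 fixed gene lists called higher (red, to the right) or lower (blue, to the left) in each of the 4 comparisons in the authors' deposited table, with the number of measured members in brackets. In transplanted TAµ against transplanted µ, 19 of 28 homeostatic microglia genes are lower and 11 of 18 marrow-derived macrophage genes higher.

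P10 TAµ and adult control µ were compared last, and here population and age change together. Cell division genes were higher in P10 TAµ in the authors' deposited table, with Mki67 at 5.27 ± 0.52 (adjusted p = 1.41e-06), Top2a at 5.41 ± 0.45, Kif11 at 6.40 ± 1.13 and Tpx2 at 6.36 ± 0.85. Igf1 was higher by 8.61 ± 1.33 (adjusted p = 0.000119), the osteopontin gene Spp1 by 6.55 ± 0.84 and the cyclin gene Ccnd2 by 6.74 ± 1.46 in the authors' deposited table. Mrc1 was higher by 5.80 ± 0.55, Apoe by 3.56 ± 0.45 and Ms4a7 by 4.22 ± 1.25 in the authors' deposited table, whereas H2-Aa was lower at -5.64 ± 1.32 (adjusted p = 0.00339). Of the marrow-derived macrophage list 5 of 18 genes were higher and 0 lower in the authors' deposited table, 3 and 0 adjusted over the list alone (cameraPR adjusted p = 0.577), and 3 were higher and 2 lower with centred fold changes. The neutrophil protein genes S100a8, at -4.39 ± 1.35, and S100a9, at -4.47 ± 1.33, were lower in P10 TAµ in the authors' deposited table. The other large falls were Trpm2 at -4.81 ± 0.33, Neat1 at -4.34 ± 0.33 and Csmd3 at -4.28 ± 0.28 in the authors' deposited table.

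The direction of the proliferation genes is no finding here either, as the sign was set from them. Proliferation genes were higher in 33 of 35 cases and lower in 0 in the authors' deposited table, 33 and 0 adjusted over the list alone (cameraPR adjusted p = 2.51e-20). Border-associated macrophage genes were higher in 13 of 19 cases and lower in 0 in the authors' deposited table, 13 and 0 adjusted over the list alone (cameraPR adjusted p = 1.81e-05). Amoeboid and disease-associated genes were higher in 15 of 21 cases, with Ctsl at 2.20 ± 0.20 and Ctsb at 1.87 ± 0.18, and lower in 2 in the authors' deposited table. Their counts adjusted over the list alone were 15 and 2, with a cameraPR adjusted p of 1.81e-05. Lysosome genes were higher in 19 of 30 cases, with Gusb at 1.79 ± 0.16 and Tpp1 at 1.35 ± 0.16, and lower in 0 in the authors' deposited table, 19 and 0 adjusted over the list alone (cameraPR adjusted p = 7.76e-05). Cholesterol synthesis genes were higher in 12 of 19 cases, with Hmgcs1 at 2.08 ± 0.30, and lower in 0 in the authors' deposited table. Their counts adjusted over the list alone were 14 and 0, with a cameraPR adjusted p of 0.000557. Erythroid genes were higher in 5 of 7 cases and lower in 0 in the authors' deposited table, 6 and 0 adjusted over the list alone. Their cameraPR adjusted p was 0.0408, and the adjusted p was 0.0741 with the correlation preset at 0.05.

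No cameraPR call was made for the lists given next. Astrocyte genes were higher in 3 of 13 cases and lower in 1 in the authors' deposited table, 3 and 1 adjusted over the list alone (cameraPR adjusted p = 0.96), with a median of -0.03 when centred. Pericyte and smooth muscle genes were higher in 2 of 6 cases and lower in 1 in the authors' deposited table, 3 and 2 adjusted over the list alone (cameraPR adjusted p = 0.812). Neuron genes were higher in 7 of 13 cases and lower in 0 in the authors' deposited table, 7 and 0 adjusted over the list alone (cameraPR adjusted p = 0.0812). Oligodendrocyte genes were higher in 5 of 12 cases and lower in 0 in the authors' deposited table, 5 and 0 adjusted over the list alone (cameraPR adjusted p = 0.341). Endothelial genes were higher in 4 of 7 cases and lower in 0 in the authors' deposited table, 4 and 0 adjusted over the list alone (cameraPR adjusted p = 0.209). B cell genes were higher in 3 of 4 cases and lower in 0 in the authors' deposited table, 3 and 0 adjusted over the list alone (cameraPR adjusted p = 0.0513). The p53 response genes were higher in 6 of 17 cases and lower in 1 in the authors' deposited table, 7 and 1 adjusted over the list alone (cameraPR adjusted p = 0.308), and with centred fold changes 5 were higher and 4 lower.

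MHC class II genes were lower in 5 of 12 cases and higher in 0 in the authors' deposited table, 5 and 0 adjusted over the list alone (cameraPR adjusted p = 0.000493). Neutrophil genes were lower in 9 of 12 cases and higher in 0 in the authors' deposited table, 9 and 0 adjusted over the list alone (cameraPR adjusted p = 5.16e-05). Immediate early genes were lower in 12 of 20 cases and higher in 1 in the authors' deposited table, 13 and 1 adjusted over the list alone (cameraPR adjusted p = 2.65e-08). Inflammatory cytokine genes were lower in 8 of 18 cases and higher in 0 in the authors' deposited table, 8 and 0 adjusted over the list alone (cameraPR adjusted p = 0.00244). Of 19 macrophage and microglia transcription factors 8 were lower and 3 higher, with Tfec at 6.53 ± 1.25, in the authors' deposited table. Their counts adjusted over the list alone were 9 and 3, with a cameraPR adjusted p of 0.00433. Homeostatic microglia genes went both ways, 7 higher and 6 lower of 28, with Fcrls at 1.69 ± 0.23, Mertk at -1.24 ± 0.15 and Selplg at -1.42 ± 0.24, in the authors' deposited table. Their counts adjusted over the list alone were 7 and 6, with a cameraPR adjusted p of 0.264, and with centred fold changes 1 was higher and 13 lower.

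In all, 3195 genes were higher and 1721 lower in the authors' deposited table, 65.0% of the calls being higher. The median over all genes was 0.41, and with fold changes centred on it 1875 were higher and 2801 lower, 40.1% being higher. Centring turned the medians of the marrow-derived macrophage list from 0.22 to -0.19, the interferon response list from 0.12 to -0.29 and the astrocyte list from 0.38 to -0.03. It left 8 lysosome genes higher and 1 lower. Median, mean and test differed in sign for the interferon response and stem cell lists, both without a cameraPR call. By GENCODE M21 on mm10, Ms4a7 (ENSMUSG00000024672) lies on chromosome 19 from 11321039 to 11336146 and Sall1 (ENSMUSG00000031665) on chromosome 8 from 89027235 to 89044162. Phlda3 (ENSMUSG00000041801) lies on chromosome 1 from 135766119 to 135769136 and H2-Aa (ENSMUSG00000036594) on chromosome 17 from 34282744 to 34287823, and all of these are annotated as protein-coding. Reads of H2, Ms4a6 and hemoglobin genes can be shared between close paralogs, and their values are uncertain to that extent.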

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

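The tests of the difference of effects, and all tests of explanations except those on transcript length and expression, were chosen after the results were seen. The difference from control, transplanted TAµ minus P10 TAµ, set against transplanted µ minus adult control µ, differed between the fractions for 1818 genes (TAµ minus µ, log2). The controls differ in age, and the contrast carries that difference too. The lists whose difference passed cameraPR had medians of -1.04 (homeostatic microglia), 0.61 (marrow-derived macrophage), 1.94 (monocyte), 2.03 (MHC class II), 0.56 (interferon response), -3.99 (proliferation), -1.16 (amoeboid and disease-associated microglia), 0.30 (inflammatory cytokines), 1.10 (immediate early), -1.52 (p53 response), -0.66 (lysosome), 1.99 (neutrophil) and -2.71 (dendritic cell). Centred on the median difference over all genes, these medians were, in the same order, -0.54, 1.11, 2.45, 2.53, 1.06, -3.48, -0.66, 0.80, 1.60, -1.01, -0.16, 2.5 and -2.21. The direction of the proliferation list follows the choice of sign and is no finding. Centring took the more negative genes from 9 to 4 in the lysosome list and from 7 to 3 in the amoeboid list, and the more positive ones from 3 to 5 in the interferon and from 3 to 6 in the immediate early list. The cameraPR adjusted p was 0.0464 for monocyte, 0.00939 for interferon response, 0.00899 for inflammatory cytokine, 0.00238 for immediate early, 0.00159 for lysosome, 0.00589 for neutrophil, 0.0360 for amoeboid and 0.0435 for dendritic cell genes. With the correlation preset at 0.05 the adjusted p was 0.128 for monocyte, 0.0701 for interferon, 0.128 for amoeboid, 0.0524 for inflammatory cytokine and 0.0779 for dendritic cell genes, and in the rank-based form it was 0.0799 for amoeboid and 0.184 for dendritic cell genes.

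Named genes with a more negative difference in TAµ, derived from the authors' deposited table, were Arvcf -4.48 ± 0.86, Ccnd2 -6.68 ± 1.55, Ccng1 -2.37 ± 0.42, Cd9 -2.23 ± 0.57, Cdkn1a -5.19 ± 0.71, Ctsb -1.23 ± 0.29, Ctsl -2.84 ± 0.35, Cx3cr1 -1.02 ± 0.29, Fads2 -4.80 ± 1.45, Fcrls -1.90 ± 0.38, Gusb -1.28 ± 0.27, Hmgcs1 -1.82 ± 0.41, Hmmr -7.94 ± 1.53, Itgam -1.92 ± 0.45, Layn -7.50 ± 1.15, Lpl -5.64 ± 1.03, Mki67 -5.28 ± 0.86, Mrc1 -2.68 ± 0.66, Myo18b -5.50 ± 1.68, Nfib -5.34 ± 1.26, Nid2 -10.96 ± 2.28, P2ry12 -2.50 ± 0.38, Phlda3 -8.43 ± 1.13, Pros1 -2.67 ± 0.36, Rhob -1.57 ± 0.47, Sall1 -3.08 ± 0.40, Sall3 -2.75 ± 0.65, Sgce -7.24 ± 1.17, Slc2a5 -3.47 ± 0.48, Sparc -2.99 ± 0.44, Spp1 -5.45 ± 1.64, Tmem44 -5.08 ± 1.56, Top2a -4.69 ± 0.65, Tpp1 -1.79 ± 0.27, Tpx2 -5.91 ± 1.41 and Zfp697 -6.42 ± 1.03. Those with a more positive difference, derived from the authors' deposited table, were Axl 2.55 ± 0.70, Cd74 3.78 ± 0.58, Cxcl16 3.49 ± 0.36, Cybb 3.25 ± 0.80, Fam107a 5.04 ± 1.44, Fosb 3.06 ± 0.94, H2-Aa 8.91 ± 1.42, H2-Ab1 4.45 ± 0.93, H2-DMa 2.35 ± 0.41, Neat1 5.12 ± 0.94, Nfkbiz 3.66 ± 0.95, Stab1 1.48 ± 0.29 and Trpm2 4.44 ± 0.45.

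Macrophage-list genes and p53-list genes stood higher in transplanted µ than in adult control µ. Cells like TAµ inside the sorted µ fraction could account for the macrophage genes. Of 37 members higher in transplanted TAµ than in control, 34 lie between both and 0 were called above TAµ. These members were picked for being high in TAµ, so standing below it is largely given by that choice and is no support. The log2 share needed was -5.06 ± 0.50 for Ms4a7 (3.0%) and -0.27 ± 0.36 for Maf (83.0%), and a common share of 15.1% has a Cochran Q p of 8.7e-29. This test covers 34 of the 37 members. Members not above control in transplanted µ, or without usable group variances, have no share and were left out, which can raise the common share. In the 27 genes 16-fold or more above control the pooled share was 8.7% with a Cochran Q p of 0.0081, and a gate that selects some of these cells could change their makeup, so this explanation cannot be told apart from a change in µ cells. No rule was set for a shift of the adult control libraries in the macrophage genes. Against that control P10 TAµ was also higher in 13 border-associated and 5 marrow-derived macrophage genes. Against P10 TAµ, a comparison without that control, transplanted µ was higher in 9 marrow-derived genes and lower in 2. The cameraPR adjusted p was 2.07e-07, adjusted apart from the main tests. For the marrow-derived list this argues against a shift of the adult control libraries alone as the whole account. P10 TAµ differs from transplanted µ in population and age, and a part played by such a shift cannot be told apart. Of the 7 p53 members called higher, 4 (Cdkn1a, Phlda3, Sesn2, Trp53inp1) were called above transplanted TAµ as well as above adult control µ. For these 4 members this argues against an admixture of cells with the makeup of the sorted TAµ. TAµ-like cells whose makeup the gate changed are not covered. Of the 4 members 3 (Cdkn1a, Phlda3, Trp53inp1) were also higher than in P10 TAµ, which a shift of the adult control libraries alone could not bring about. Phlda3 is the least certain of these, with an average log2 expression of 0.11, under the first quartile of 0.88. All 4 were picked for being high in transplanted µ, whose 3 libraries enter each of these comparisons. Part of their standing above the other groups is therefore given by that choice. The other p53 members (Ccng1, Zmat3, Ei24) were all 3 called above adult control µ in every other group, and the list had medians of 1.36 in transplanted µ, 1.31 in P10 TAµ and 1.25 in transplanted TAµ against that control, so for them neither explanation can be told apart from effects of treatment, transplantation and age, which stay untested.

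Immediate early genes stood higher in adult control µ than in the other groups. Handling of the adult control libraries alone is argued against as the whole account. Against P10 TAµ, a comparison without that control, 12 of 20 members were lower in transplanted TAµ and 12 in transplanted µ. A part played by such handling cannot be told apart, as 10 of 20 members were lower than in that control in all 3 other groups. A bias of transcript length or expression is argued against by the median of -3.41, below the lower bound of 0.04 of 10000 lists matched on both. A difference in handling or day between the mice of each group could account for the pattern and cannot be told apart, as the fractions of the transplanted mice differed by a median of -0.2. Treatment and age also stay open, as untested.

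Neural transcripts stood higher in transplanted fractions than in controls, except for the oligodendrocyte list in TAµ against P10 (median -0.13, cameraPR adjusted p = 0.0732). Taken as a single list, they were also high in P10 TAµ against adult control µ, with a median of 1.98 above an upper bound of 0.95 in matched lists. By list, the medians in P10 TAµ against that control were 2.78 for neuron, 2.09 for oligodendrocyte and 0.38 for astrocyte genes, without a cameraPR call. Astrocyte genes had 3 members higher and 1 lower there, against a median of 2.45 in transplanted µ. The rise against that control thus cannot be called particular to transplanted µ for neuron and oligodendrocyte genes, whereas astrocyte genes hardly shared it. A shift of the adult control libraries was not tested here. That control plays no part in TAµ against P10, where the single list had a median of 1.76, with an upper bound of 0.12 in matched lists. A bias of transcript length or expression is argued against by the median of 2.61 in transplanted µ, above an upper bound of 0.59 in matched lists. RNA of adult neurons and glia in the sorted fractions cannot be told apart. Of 16 abundant neural markers 10 were called higher in transplanted µ and 14 in transplanted TAµ against their controls, and 10 in both. This is the largest overlap these calls allow, against 8.75 by chance. Its exact hypergeometric p of 0.125 is therefore the smallest that the test could give, and the test cannot decide the question. A lower share of myeloid cells of every kind cannot be told apart: neural markers had a median of 2.61 and vascular markers of -0.40, a gap of 3.01 (permutation p = 6e-05), but the vascular markers have a median average expression of -0.03, under the first quartile of 0.88. How many of these markers myeloid cells also express was not tested, and treatment and age stay open.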

How the results depend on the processing

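The median-centred and median-expression settings were chosen after the results were seen. Counts of genes past adjusted p 0.05, in the order transplanted µ against control, transplanted TAµ against P10, TAµ against µ, P10 against control and interaction, were 2997, 3541, 894, 4916 and 1818. They were 1155, 1849, 274, 2817 and 547 at threshold 0.01, and 127, 331, 52, 483 and 71 with Bonferroni adjustment, by construction. A filter at the median expression left 1847, 1670, 494, 2786 and 1324, through fewer genes tested. Recomputed adjustment and 1 entry per symbol changed nothing, the first-quartile filter and the minimum fold stayed within 1.5 times, and list calls were 57 of 125, with 61 at preset 0, 46 at preset 0.05 and 56 by rank. No named gene that was called turned direction, while centring turned the sign of the uncalled differences of Trem2 (µ against control), Tmem119 (TAµ against P10), Mki67 (TAµ against µ) and Cx3cr1 (P10 against control), and 23 of 149 named results lost their call at threshold 0.01, 70 with Bonferroni adjustment, 8 with the minimum fold and 2 (Cx3cr1 and Cdkn1a, TAµ against P10) with either expression filter, which left 3 and 22 named results untested. With centring 140 named results kept their side of the threshold, 5 became weaker (Itgam, Cdkn1a, P2ry12 and Cx3cr1 in a pair of comparisons) and 4 stronger, and the cause was not tested. No paired analysis was possible because the table holds no values per library, which also ruled out other normalizations, a pseudocount, fits of compared groups alone, trend and robust fits, leaving out replicates, a block on the sample letter, draws of 3 P10 libraries, estimated correlation and fry. What depth limits was not tested, as totals per library were not analysed here.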

Other observations

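These values were chosen after the results were seen. Malat1 was lower in P10 TAµ at -2.80 and in transplanted TAµ at -4.12 against adult control µ in the authors' deposited table. The mitochondrial gene mt-Co1 was higher in transplanted TAµ than in P10 TAµ by 1.89 in the authors' deposited table. The Y-linked genes had large recovered interaction standard errors, Ddx3y 3.75, Uty 3.15, Kdm5d 3.38 and Eif2s3y 3.56, against a median of 0.88 at similar expression. That of the X-linked RNA Xist was 7.07. The sex of the libraries was not analysed here. None of the differences of the Y-linked genes was called, as for Ddx3y at -5.54 (adjusted p = 0.230) between transplanted and adult control µ in the authors' deposited table. Of the T and NK cell list only Cd4 was measured, too few for a test, with a difference of 5.27 between transplanted TAµ and µ in the authors' deposited table. The fold changes of TAµ against µ in transplanted mice and of P10 TAµ against adult control µ correlated across genes, which are not independent, with a Pearson r of 0.22 and a Spearman rho of 0.2. In both, 185 genes were higher, against 113.7 for independent lists, and 122 lower, against 50.5, in the authors' deposited table.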
